A study of Mus musculus with 8 samples.

How the data were processed

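Bulk RNA sequencing was used to measure gene expression in the thoracic aortas of 8 male C57BL/6 mice at 24 weeks of age. All mice carried Myh11-CreERT2, a tamoxifen-inducible Cre recombinase made in smooth muscle cells, together with the mT/mG fluorescent reporter, and were given tamoxifen at 1.5 weeks. In 4 mice both Tsc1 alleles were floxed, so that recombination removes Tsc1 from smooth muscle (Tsc1 knockout), and in 4 mice Tsc1 was wild type (control). Per the labels' protocols, whole aortas were flash frozen and crushed, 500 ng of total RNA with a RIN above 7 was selected for polyA tails, and libraries were prepared by standard Illumina methods. The labels name smooth muscle cells as the cell type, but the protocol describes no sorting, so the RNA is that of the whole vessel wall with any tissue attached to it. The labels number the libraries of each group as replicates 1 to 4 and none says that several mice were pooled, so the replicates are taken as separate animals. Where that does not hold, the p-values measure only the spread between these samples, which may be technical.

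The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 column per library, for 23993 gene symbols, each on a single row. TopHat2, Cufflinks, Cuffdiff and the mouse build mm10 are named per the submitters' processing notes, without versions or roles. The gene annotation, the strand setting and any scaling between libraries are not given in the sources used here. FPKM from fragments assigned to gene models by estimation do not separate fragments shared by near-identical genes or by overlapping antisense genes, so values of such families (hemoglobins, Hspa1a and Hspa1b, ribosomal protein genes with processed pseudogenes) are less certain than those of single-copy genes. All columns of per-sample values were used. Read counts were not analysed here.

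Depth was read from the FPKM only in relative terms. Among genes under 0.3 FPKM, the most frequent ratio of values between each library and control 1, taken as the ratio of what 1 fragment is worth, put the other libraries between 0.766 (Tsc1 knockout 1) and 2.44 times (control 3) the depth of control 1. That mode held 6.94% to 11.9% of the compared low genes, so it is a rough figure, and the absolute depth is unknown. The sums of the FPKM columns ran from 453564 to 937271. In the 3 libraries with the highest sums a single small RNA row took much of the total: Scarna17 had 446002 FPKM in control 2, Mir7036 had 267696 in control 1 and Mir3064 had 101808 in control 3. Transcripts shorter than the selected fragments can get such values from very few fragments. Without the small RNA rows the sums ran from 481978 to 490079 in controls and from 451982 to 466803 in knockouts, without overlap between the groups. Median-of-ratios factors over expressed genes ran from 0.986 to 1.01, so the values were compared as deposited.

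Values were transformed as log2(FPKM + 1), a scale that understates the change of low genes. The 12107 genes with a mean of at least 1 FPKM over the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), two-sided, with genotype as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p printed for a gene comes from that fit, except where another fit is named. Fold differences are printed as log2 differences, knockout minus control, with the standard error (SE) from the moderated variance. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list's members with all other tested genes, with Benjamini-Hochberg adjustment over the 30 lists that had at least 3 tested members. A list score was the mean of log2(FPKM + 1) over the tested members in each library, and scores were compared by a two-sided exact permutation test over the 70 assignments of 4 and 4 libraries, whose smallest p is 0.0286. The test, the filter, the alternatives, the 31 gene lists and the rule for named genes were fixed before the data were examined.

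The gene lists were contractile smooth muscle, modulated smooth muscle, chondrocyte and bone, lysosomal hydrolases and membrane proteins, lysosomal proton pump, MiT/TFE factors and regulatory targets, autophagy machinery, glycolysis and pentose phosphate, sterol biosynthesis, fatty acid synthesis, ATF4 amino acid response, ER chaperones and folding, cytosolic ribosomal proteins, oxidative phosphorylation, fibrillar and basement membrane collagens, elastic fibre, matrix proteases, TGF-beta signalling and targets, macrophage markers, T, B and NK cell markers, chemokines and cytokines, interferon response, MHC class II presentation, endothelial markers, adventitial fibroblast markers, fat cell markers, striated muscle markers, Schwann cell and neuron markers, red blood cell markers, immediate early genes, and cell cycle. The rule for named genes took Tsc1 and Tsc2. It also took the 6 called genes with the largest log2 difference in each direction among those whose 4 knockout libraries all lay above or all below the 4 controls, leaving out small RNAs, unnamed gene models and rows that join several symbols. From each list called by camera it took the 2 called members with the largest absolute log2 difference, and from each other list the 1 called member with the largest. It named 52 genes, of which 1 is not reported here. Other genes named below were chosen after their values were seen, mostly as familiar members of the fixed lists.

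The fit was tested on simulated data made from the 12107 genes' own means and spread, with 200 genes changed. Over 20 runs, 60.8% of genes changed by 0.5 (log2), 89.8% of those changed by 1 and 98.6% of those changed by 2 were called. Of the calls 4.23% were false, and a list shifted by 0.3 was called by camera in 20 of 20 runs. Noise was drawn for each gene alone, so the simulation holds no correlation between genes. It therefore does not test the share of false calls, or camera's preset correlation, where genes vary together. Alternatives were other pseudocounts (0.1 and 0.5) and filters (none, 0.1 and 5 FPKM), median-of-ratios and quantile scaling, eBayes without trend and with robust fitting, library weights, the replicate number as a block, the fat cell score as a covariate, removal of small RNA rows, a minimum log2 change of 1, camera with an estimated correlation, limma's fry, exact permutation of list scores, and each library left out in turn. After the data were seen, fits with odd against even replicate number as a covariate, and within the odd-numbered and the even-numbered libraries alone, were added, because those libraries separated on the second principal component in both groups. Coordinates are those of GENCODE M21, which uses the same assembly as mm10, and 11590 of the 12107 tested symbols matched it. Figures were drawn with matplotlib 3.10.9.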

Results

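Gene expression was measured by RNA sequencing in 8 thoracic aortas of male mice at 24 weeks of age, 4 controls and 4 with Tsc1 removed from smooth muscle by tamoxifen-induced Cre at 1.5 weeks. Tsc1 encodes hamartin, which with tuberin (Tsc2) restrains the growth kinase mTORC1, and the single comparison asks how the aorta differs once smooth muscle lacks it. Values are the deposited FPKM, given as mean ± SD with n = 4 per group unless stated otherwise. Between 11867 and 12083 genes reached 1 FPKM in each library, and the relative depth of the libraries ran from 0.766 to 2.44 with control 1 at 1.

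In the knockout aortas 28 of 39 lysosomal hydrolase and membrane protein genes and 16 of 16 genes of the lysosomal proton pump rose, while 17 of 25 contractile genes, 15 of 23 genes of collagens and collagen-modifying enzymes, 40 of 42 ribosomal protein genes and 12 of 17 endothelial markers fell. Spp1 (osteopontin, a secreted matrix phosphoprotein) rose from 1.37 ± 0.898 to 39.7 ± 26.3 FPKM. Gpnmb, a membrane glycoprotein induced by MiT/TFE transcription factors, rose from 5.11 ± 0.412 to 48.7 ± 12.5 FPKM. Eln (elastin) fell from 1012 ± 375 to 374 ± 134 FPKM, and Cnn1 (calponin, a contractile protein) fell from 1138 ± 105 to 541 ± 129.7 FPKM. Of 12107 genes tested with limma, 2074 were higher and 1819 lower in the knockout, 32.2% of the tested genes. The log2 difference was at least 1 in size for 206 of the higher and 161 of the lower genes. All 4 knockout libraries lay above all 4 controls for 1924 of the higher genes and below them for 1672 of the lower genes. Over all tested genes 33.9% had no overlap between groups, against 2.86% by chance.

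The first principal component, with 44.8% of the variance, separated the genotypes. The second, with 16.6%, separated replicates 1 and 3 from replicates 2 and 4 within both genotypes. Pearson's r of log2 values across genes, which are not independent replicates, was 0.967 to 0.984 between libraries of one genotype and 0.944 to 0.963 between genotypes. Within the odd-numbered libraries alone (2 against 2) 1649 genes were higher and 1453 lower, and within the even-numbered libraries 1611 and 1494. With odd or even number as a covariate the counts were 2636 and 2353. The genotype difference itself differed between odd and even numbers for 196 genes (limma interaction), 5 of 25 contractile and 6 of 18 modulated smooth muscle genes among them.

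**Figure D1:**
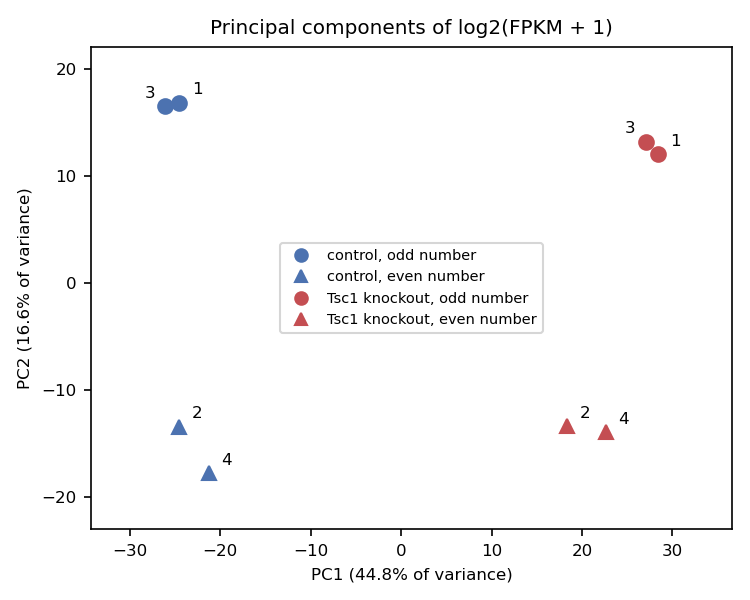
Principal components 1 and 2 of log2(FPKM + 1) over the 12107 tested genes, 1 point per aorta, with the replicate number beside it. Controls lie at -26.1 to -21.3 and knockouts at 18.4 to 28.4 on component 1, and odd and even numbers lie apart on component 2 in both groups.

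Tsc1 itself (chromosome 2, 28641228 to 28691167 in mm10) had 4.03, 4.82, 4.95 and 6.32 FPKM in controls 1 to 4 and 2.99, 3.58, 3.37 and 3.71 in knockouts 1 to 4. It fell from 5.03 ± 0.952 to 3.41 ± 0.315 FPKM (log2 difference -0.44, SE 0.12, adjusted p = 0.019), below the controls in 4 of 4 knockout libraries. Its partner Tsc2 (chromosome 17, 24595816 to 24632630) fell from 39.4 ± 3.55 to 32.7 ± 1.23 FPKM (log2 difference -0.26, SE 0.07, adjusted p = 0.0214). FPKM over the whole gene also count transcripts of the recombined allele that keep their other exons, and transcripts of cells without Cre. The Tsc1 call was lost within the odd-numbered libraries alone (log2 difference -0.39) and within the even-numbered ones alone (-0.49). The Tsc2 call was lost within the odd-numbered ones (-0.16) and without knockout 4 (-0.23).

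The largest rise among the genes taken by the fixed rule was that of Ptgds, the lipocalin-type prostaglandin D synthase, from 0.609 ± 0.413 to 48.7 ± 18.8 FPKM (log2 difference 4.90, SE 0.28, adjusted p = 1.68e-05). Spp1 came next (log2 difference 3.90, SE 0.49, adjusted p = 6.02e-04), followed by Fetub, a secreted fetuin, which rose from 1.46 ± 0.156 to 41.3 ± 32.3 FPKM (log2 difference 3.71). Kcnk3, the two-pore potassium channel TASK-1, rose from 5.13 ± 1.03 to 68.3 ± 14.4 FPKM (3.49). Actc1 (cardiac alpha-actin) rose from 1.5 ± 0.688 to 24 ± 14.5 FPKM (3.17), and the transcription factor Sox4 rose from 6.87 ± 1.56 to 67.3 ± 19.6 FPKM (3.09). The 4 knockout libraries were far apart for several of these. Spp1 had 61.3, 18.4, 63.6 and 15.5 FPKM in knockouts 1 to 4, Fetub 59.9, 13.6, 77.3 and 14.6, and Actc1 36.2, 11.7, 11.3 and 36.9. The 2 knockouts with the higher Actc1, numbers 1 and 4, also had the higher striated muscle marker scores (2.45 and 2.44, against 1.20 and 1.30). Control 4, however, with the highest score of all 8 libraries (3.86), had the lowest Actc1 (0.549 FPKM). In mm10 these genes lie on chromosome 2, 25466709 to 25470046 (Ptgds), chromosome 5, 104435118 to 104441050 (Spp1), chromosome 16, 22918334 to 22939778 (Fetub), chromosome 5, 30588170 to 30625271 (Kcnk3), chromosome 2, 114047282 to 114053548 (Actc1) and chromosome 13, 28948919 to 28953713 (Sox4).

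Casq1, a calcium-binding protein of the sarcoplasmic reticulum, had the largest fall under the same rule, from 66 ± 10.2 to 4.21 ± 2.29 FPKM (log2 difference -3.79, SE 0.31, adjusted p = 7.95e-05). The Wnt inhibitor Wif1 fell from 29 ± 8.75 to 2.18 ± 1.79 FPKM (log2 difference -3.38), the membrane protein gene Vstm2b fell from 12.7 ± 2.53 to 0.944 ± 0.263 FPKM (-2.80), and P2rx1, an ATP-gated cation channel of smooth muscle, fell from 27.2 ± 2.13 to 4.23 ± 2.29 FPKM (-2.54). Bves, which encodes a membrane protein of muscle cells, fell from 11.4 ± 0.185 to 1.66 ± 1.03 FPKM (-2.31), and Fam46b fell from 22.6 ± 10.8 to 3.56 ± 1.8 FPKM (-2.26). Fam46b had 30, 28.1, 25.7 and 6.65 FPKM in controls 1 to 4, and its call was lost within the even-numbered libraries alone (-1.34). Coordinates in mm10 are chromosome 1, 172209894 to 172219868 for Casq1, chromosome 10, 121033960 to 121100650 for Wif1, chromosome 7, 40898328 to 40930594 for Vstm2b, chromosome 11, 72999103 to 73015200 for P2rx1 and chromosome 10, 45335772 to 45372479 for Bves, while the symbol Fam46b did not match the annotation.

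**Figure D2:**
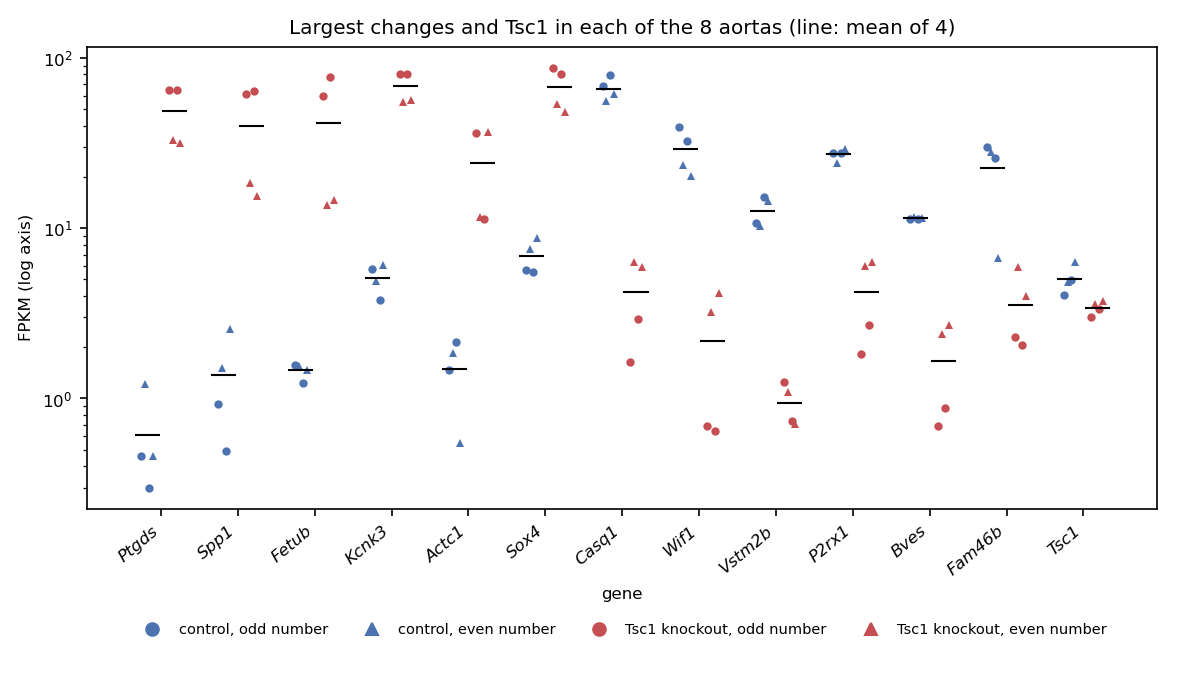
FPKM on a log axis for the 6 genes with the largest rise and the 6 with the largest fall under the fixed rule, and Tsc1, 1 point per aorta (4 controls, 4 Tsc1 knockouts, odd and even replicate numbers by shape) with a line at each group mean. Spp1 is at most 2.56 FPKM in controls and at least 15.5 in knockouts, and Casq1 at least 55.7 in controls and at most 6.35 in knockouts.

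Of the 30 gene lists tested with camera, 6 were higher and 8 lower in the knockout. The score of each of these 14 lists differed between groups with an exact permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and 0.0536 after adjustment over the lists. The uncalled lists of modulated smooth muscle and of chondrocyte and bone genes reached the same values. Only the lysosomal proton pump list kept its call with an estimated correlation between genes. Of the 18 other divisions with 2 libraries of each genotype on each side, most called at least 4 lists. At least 14 were called by 2 of them, 1 being odd against even numbers with 17.

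Lysosomal genes rose as a group. All 16 tested subunits and partners of the proton pump that acidifies lysosomes were higher (16 higher and 0 lower adjusted over the list alone), with a median log2 difference of 0.48 (camera adjusted p = 1.35e-09, and adjusted p = 0.0138 with an estimated correlation). Atp6v1b2 rose from 17.7 ± 1.2 to 30.8 ± 1.34 FPKM and Atp6v1a from 39.6 ± 0.398 to 66 ± 9.06 FPKM, both subunits of the cytosolic part of the pump. Of 39 lysosomal hydrolases and membrane proteins, 28 rose, 1 fell and 10 did not pass (34 higher and 1 lower adjusted over the list alone), with a median of 0.44 (camera adjusted p = 4.82e-12, but adjusted p = 0.114 with an estimated correlation). Lipa (lysosomal acid lipase) rose from 21 ± 1.9 to 41.7 ± 5.02 FPKM, Lamp2 (a lysosomal membrane protein) from 65.1 ± 3.83 to 123 ± 6.01 FPKM and Ctsd (cathepsin D) from 446 ± 10.7 to 595 ± 30.1 FPKM. Ctsf (cathepsin F) was the member that fell (log2 difference -0.31).

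Of 14 MiT/TFE factors and their regulatory targets, 9 rose and 1 fell (9 higher and 1 lower adjusted over the list alone; median 0.53; camera adjusted p = 1.59e-04, adjusted p = 0.195 with an estimated correlation). Gpnmb had a log2 difference of 2.99 (SE 0.17, adjusted p = 1.68e-05), and Rragd, a Rag GTPase that signals amino acids to mTORC1, rose from 0.645 ± 0.14 to 8.69 ± 2.24 FPKM (2.53). Flcn (0.60) and Fnip1 (0.76), partners that act on Rag GTPases, also rose. Of the factors themselves, Mitf rose from 6.11 ± 0.329 to 7.93 ± 0.694 FPKM (adjusted p = 0.00932), Tfe3 had a log2 difference of 0.05 and did not pass, and Tfeb was the member that fell, from 19.2 ± 4.05 to 13.8 ± 1 FPKM (adjusted p = 0.0376). The Tfeb call was lost in 8 alternatives, among them leaving out any 1 library but control 1 or control 3 (log2 differences from -0.53 to -0.34 over all 8 libraries left out in turn), and the Mitf call was lost within the even-numbered libraries alone (0.19). Of 20 autophagy genes 7 rose and 1 fell (7 higher and 1 lower adjusted over the list alone; median 0.11; camera adjusted p = 0.003, adjusted p = 0.195 with an estimated correlation). Gabarapl1 rose from 158 ± 14.8 to 327 ± 17.7 FPKM and Map1lc3b from 159 ± 14.1 to 260.0 ± 14.9 FPKM, both ubiquitin-like proteins of the autophagosome membrane, and Map1lc3a fell (log2 difference -0.57).

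Among metabolic lists, glycolysis and the pentose phosphate pathway had 11 genes higher, 0 lower and 10 that did not pass (11 higher and 0 lower adjusted over the list alone; median 0.23; camera adjusted p = 0.0137, adjusted p = 0.243 with an estimated correlation). Eno1 (enolase) rose from 90.4 ± 8.14 to 134 ± 8.84 FPKM and the glucose transporter Slc2a1 from 31 ± 4.77 to 45 ± 1.18 FPKM. This list's call was also lost within the odd-numbered libraries alone (camera adjusted p = 0.117). Of 23 sterol biosynthesis genes 9 rose and 0 fell (10 higher and 0 lower adjusted over the list alone; median 0.32; camera adjusted p = 8.09e-04, adjusted p = 0.388 with an estimated correlation). Insig1, a sterol sensor of the endoplasmic reticulum, rose from 13.4 ± 4.58 to 29.1 ± 6.49 FPKM, and the methylsterol monooxygenase gene Msmo1 from 16.6 ± 2.31 to 27.7 ± 3.35 FPKM. The Insig1 call was lost within the even-numbered libraries alone (log2 difference 0.98).

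Fatty acid synthesis was not called (camera adjusted p = 0.545). Of its 15 genes 3 rose and 0 fell (3 higher and 0 lower adjusted over the list alone), with a median of -0.02 and a mean of 0.05. Acacb (acetyl-CoA carboxylase 2) rose from 4.99 ± 2.26 to 10.2 ± 2.15 FPKM, with control 1 at 8.36 FPKM and the other controls at 3.55 to 4.20. Its call was lost within the odd-numbered libraries alone (log2 difference 0.86). Oxidative phosphorylation was not called (camera adjusted p = 0.203), with 4 of 31 genes higher, 0 lower and a median of 0.06 (3 higher and 0 lower adjusted over the list alone). Cox5a, a subunit of cytochrome oxidase, rose from 89.2 ± 7.27 to 111 ± 5.57 FPKM. The ATF4 amino acid response was not called (camera adjusted p = 0.403), with 6 higher, 3 lower and 13 that did not pass (7 higher and 3 lower adjusted over the list alone). Gdf15, a stress-induced cytokine, rose from 1.52 ± 0.638 to 24.8 ± 23.4 FPKM (adjusted p = 0.0048), and the serine synthesis enzyme genes Psat1 (0.88) and Phgdh (0.70) rose, while Atf4 fell from 129.7 ± 12.2 to 93.1 ± 12.3 FPKM. Of 19 ER chaperone and folding genes, Canx (calnexin) alone rose, from 105 ± 2.44 to 139 ± 4.61 FPKM, and the list was not called (camera adjusted p = 0.105; 1 higher and 0 lower adjusted over the list alone). It was called as higher in 10 alternatives, among them without control 3, knockout 2 or knockout 4 (camera adjusted p = 0.0462, 0.0172 and 0.00356) and within the odd-numbered libraries (8.01e-06). The others were the fits without a filter and with quantile scaling, library weights, the replicate block, the fat cell covariate or odd or even number as a covariate (0.0336 to 0.0448). Oxidative phosphorylation was called as higher without control 1 (0.0222), with quantile scaling (0.0108), with the fat cell covariate (0.0230) and within the even-numbered libraries (0.00184). Fatty acid synthesis was called as higher within the even-numbered libraries (0.0460).

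Transcripts of ribosomal proteins fell almost throughout. Of 42, 40 fell, 0 rose and 2 (Rpl34 and Rpl30) did not pass (0 higher and 40 lower adjusted over the list alone), with a median log2 difference of -0.49 (camera adjusted p = 2.52e-23, adjusted p = 0.195 with an estimated correlation). Rps14 fell from 1102 ± 109.5 to 684 ± 61.3 FPKM and Rps20 from 984 ± 49 to 623 ± 47.3 FPKM. Over the alternatives their log2 differences ran from -0.79 to -0.37 (-0.69 in the main fit) and from -0.71 to -0.34 (-0.66), with both calls kept throughout. The list score differed by -0.49 among the odd-numbered and -0.51 among the even-numbered libraries.

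Contractile genes of smooth muscle fell. Of 25, 17 fell, 1 rose and 7 did not pass (1 higher and 18 lower adjusted over the list alone), with a median of -0.51 (camera adjusted p = 8.24e-07, adjusted p = 0.398 with an estimated correlation). Ppp1r14a, an inhibitor of myosin phosphatase, fell from 845 ± 35.5 to 293 ± 81.4 FPKM (log2 difference -1.57), Pdlim7, a PDZ and LIM domain protein of the actin cytoskeleton, from 259 ± 12 to 116 ± 18.6 FPKM (-1.16), Cnn1 by 1.10 and Myh11 (smooth muscle myosin heavy chain) from 1716 ± 93.4 to 1027 ± 249.7 FPKM (-0.77). Tagln (-0.45, adjusted p = 0.0206) and Acta2 (-0.28, adjusted p = 0.026), which encode SM22 and smooth muscle alpha-actin, fell less on the log2 scale. The score fell in both sets of libraries, with differences of -0.76 among the odd-numbered and -0.26 among the even-numbered libraries. The Acta2 call was lost in 10 alternatives. Among them were the replicate block (-0.28), the even-numbered libraries alone (-0.10), quantile scaling (-0.64) and leaving out control 1, control 3, knockout 1 or knockout 3 (-0.27 to -0.23). The Tagln call was lost in 5 (even-numbered libraries -0.30, and without control 2, control 4 or knockout 3 -0.43 to -0.39), and the Myh11 call with quantile scaling (-0.47).

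The list of modulated smooth muscle genes, those expressed by smooth muscle cells that have left the contractile state, was split. Of 18 genes, 6 rose, 6 fell and 6 did not pass (6 higher and 7 lower adjusted over the list alone), with a median of 0.23, a mean of 0.50 and no call (camera adjusted p = 0.744). The genes that rose included Spp1, Tnfrsf11b (osteoprotegerin, a decoy receptor), from 6.54 ± 0.449 to 43.1 ± 16 FPKM, Mgp (matrix Gla protein, an inhibitor of calcification), from 4622 ± 1343 to 13055 ± 2629 FPKM, and the adhesion molecule Vcam1 (1.49). Those that fell included Ly6a (-1.07), Cd44 (-0.82) and Fn1, fibronectin (-0.52). The log2 difference of Mgp ran from 0.91 to 3.07 over the alternatives (1.52 in the main fit), with its call kept throughout. Lum (lumican) had a log2 difference of 0.38 and did not pass (adjusted p = 0.238). It was called without knockout 2 (0.59), within the odd-numbered libraries (0.57) and with the replicate block. The score differed by 0.80 among the odd-numbered and 0.20 among the even-numbered libraries. Of 12 chondrocyte and bone genes 1 rose and 5 fell, without a list call (camera adjusted p = 0.122; 2 higher and 5 lower adjusted over the list alone). Sox9, the transcription factor of cartilage, rose from 2.49 ± 1.22 to 7.4 ± 1.81 FPKM, while Acan, the proteoglycan aggrecan (-1.23), and Alpl, alkaline phosphatase (-0.89), fell. The chondrocyte and bone list was called as lower at a mean of 5 FPKM (camera adjusted p = 0.0213), with the replicate block (0.0284), with odd or even number as a covariate (0.0439) and with fry (adjusted p = 0.00325).

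Collagens and the elastic fibre fell. Markers of adventitial fibroblasts, which also make collagen, fell as well (median -0.40), and whole-tissue RNA does not separate fewer such cells from less matrix expression per cell. Of 23 collagens and collagen-modifying enzymes 15 fell and 0 rose (0 higher and 15 lower adjusted over the list alone), with a median of -0.72 (camera adjusted p = 2.33e-08, adjusted p = 0.0996 with an estimated correlation). Col15a1 fell from 169.5 ± 12.9 to 54.2 ± 6.22 FPKM and Col18a1 from 692 ± 83.7 to 261 ± 57.5 FPKM, both basement membrane collagens, and the fibrillar Col3a1 fell from 400.3 ± 80.8 to 167 ± 21.3 FPKM and Col1a1 from 438 ± 51.5 to 242 ± 42.1 FPKM. Lox, which crosslinks collagen and elastin, had a log2 difference of -0.77 and did not pass (adjusted p = 0.118). It was called within the odd-numbered (-0.52) and the even-numbered (-1.02) libraries alone, and with the replicate number as a block or odd or even number as a covariate (-0.77 in both). Of 17 elastic fibre genes 13 fell and 0 rose (1 higher and 13 lower adjusted over the list alone; median -0.59; camera adjusted p = 3.78e-05, adjusted p = 0.268 with an estimated correlation). Eln had 1049.9, 615, 1506 and 876 FPKM in controls 1 to 4 and 419, 228, 538 and 312 in the knockouts (log2 difference -1.43), Mfap5, a microfibril protein, fell from 178 ± 43 to 73.7 ± 6.04 FPKM, and Fbn1 (fibrillin-1) from 54 ± 5.09 to 35.4 ± 1.47 FPKM.

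Matrix proteases moved in both directions, 3 higher and 9 lower of 22 (4 higher and 9 lower adjusted over the list alone; median -0.22), and camera called the list lower (adjusted p = 0.0457, adjusted p = 0.509 with an estimated correlation). The secreted protease Adamts1 fell from 52.9 ± 29.7 to 16.6 ± 4.16 FPKM, Plat (tissue plasminogen activator) fell (log2 difference -1.21), and the membrane metalloprotease Mmp16 rose from 1.98 ± 0.245 to 7.23 ± 1.4 FPKM. Mmp9 had a log2 difference of -0.11 and did not pass (adjusted p = 0.523). The list call was lost in 11 alternatives, among them leaving out control 3, knockout 2 or knockout 4 (camera adjusted p up to 0.129), and the Adamts1 call within the even-numbered libraries alone (-1.33). TGF-beta signalling and its targets were not called (camera adjusted p = 0.157), with 3 of 19 higher and 7 lower (3 higher and 7 lower adjusted over the list alone). With fry the list was lower (adjusted p = 0.0108). Ltbp2, which also belongs to the elastic fibre list, fell from 29.7 ± 1.44 to 13.2 ± 4.08 FPKM, Postn, the matrix protein periostin, fell (-1.12), and the ligand Tgfb1 (0.61) and the receptors Tgfbr1 (0.39) and Tgfbr2 (0.46) rose.

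Markers of other cells of the vessel wall were examined because the tissue was not sorted. Of 17 endothelial markers 12 fell and 1 rose (1 higher and 12 lower adjusted over the list alone; median -0.75; camera adjusted p = 1.10e-05, adjusted p = 0.172 with an estimated correlation). Cldn5, a tight junction protein, fell from 21.6 ± 2.39 to 9.88 ± 3.8 FPKM, Pecam1 (CD31) from 144 ± 29.6 to 73.5 ± 21.6 FPKM, and Vwf (von Willebrand factor) from 22.7 ± 2.84 to 12.8 ± 2.06 FPKM. Flt1 (VEGF receptor 1) rose from 3.96 ± 0.468 to 13.1 ± 2.38 FPKM. The Cldn5 call was lost within the odd-numbered libraries alone (log2 difference -0.62). Of 16 adventitial fibroblast markers 8 fell and 0 rose (1 higher and 9 lower adjusted over the list alone; median -0.40; camera adjusted p = 0.00168, adjusted p = 0.398 with an estimated correlation), among them Ly6c1, from 49.8 ± 2.59 to 21.1 ± 3.39 FPKM, and Mfap5. Of 9 Schwann cell and neuron markers 6 fell and 0 rose (0 higher and 6 lower adjusted over the list alone; median -0.46; camera adjusted p = 0.00257, adjusted p = 0.114 with an estimated correlation), among them Stmn2, a tubulin-binding protein of neurons, from 4.17 ± 1.06 to 1.33 ± 0.465 FPKM.

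Macrophage markers were not called as a list (camera adjusted p = 0.171), with 0 of 22 higher, 2 lower and a median of -0.21 (0 and 0 adjusted over the list alone). Trem2, a macrophage receptor, fell from 2.48 ± 0.505 to 1.4 ± 0.524 FPKM (adjusted p = 0.0415), a call lost in 10 alternatives, among them leaving out any 1 library but control 4 or knockout 3, and Csf1r (-0.20) and Lyz2 (-0.24) did not pass. The list was called lower without control 4 (camera adjusted p = 0.0335) and without knockout 1 (0.0483). It was also called lower with the replicate block (0.0283), with odd or even number as a covariate (0.0256), within the odd-numbered libraries (0.0394) and at a mean of 5 FPKM (0.0466). Lyz2 was called with the block, with the covariate and within the even-numbered libraries (-0.27), and Csf1r with the covariate. Chemokines and cytokines were not called (camera adjusted p = 0.422), with 1 of 13 higher and 4 lower (1 higher and 4 lower adjusted over the list alone), and Cx3cl1 (fractalkine) rose from 8.43 ± 1.62 to 22.5 ± 7.15 FPKM. The interferon response was not called (camera adjusted p = 0.233), with 5 of 17 higher and 1 lower (5 higher and 1 lower adjusted over the list alone), and Ifit2, an interferon-induced RNA-binding protein, rose from 6.48 ± 0.631 to 19.7 ± 2.12 FPKM. The interferon list was called as higher with fry (adjusted p = 0.0341) and with the fat cell covariate (camera adjusted p = 0.0483). MHC class II presentation had 0 of 6 genes called (camera adjusted p = 0.623; 0 and 0 adjusted over the list alone). Of the T, B and NK cell markers 1 gene, Cd79a, reached 1 FPKM on average, so the list was not tested, and Cd79a did not pass (log2 difference -0.45).

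For fat cell, striated muscle and red blood cell markers and for immediate early genes, the group difference of the list score was smaller than the SD among the 4 controls. Fat cell markers had a median of -0.46 and no call (camera adjusted p = 0.122), with 0 higher and 1 lower of 16 (0 and 0 adjusted over the list alone). The adipocyte hormone Retn fell from 10 ± 5.08 to 4.21 ± 1.74 FPKM, a call lost in 8 alternatives. Among them were the replicate block and the fits without control 1 (log2 difference -0.75), control 4, knockout 1, knockout 2 or knockout 4. Striated muscle markers (median -0.90, camera adjusted p = 0.977) had 2 of 15 higher, Actc1 and Tnnt2, and 1 lower, Ckm (2 higher and 1 lower adjusted over the list alone). Red blood cell markers (0 of 6 called, median -1.42, camera adjusted p = 0.196) and immediate early genes (0 of 19 called, median -0.18, camera adjusted p = 0.266) were not called, with 0 and 0 adjusted over each list alone. For immediate early genes the camera adjusted p was 0.00619 without knockout 3 and 4.78e-04 within the even-numbered libraries, both as lower. For red blood cell markers it was 0.0372 without knockout 3 and 0.0283 with the replicate block, and for fat cell markers 0.0173 without knockout 3 and 0.0445 without control 2, all as lower. Of 12 cell cycle genes 4 rose and 1 fell, without a list call (camera adjusted p = 0.11; 5 higher and 2 lower adjusted over the list alone), and the transcription factor E2f1 rose from 1.45 ± 0.197 to 2.88 ± 0.507 FPKM. The cell cycle list was called as higher without a filter (camera adjusted p = 1.52e-04), at a mean of 0.1 FPKM (0.00109) and with fry (adjusted p = 0.00724).

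**Figure D3:**
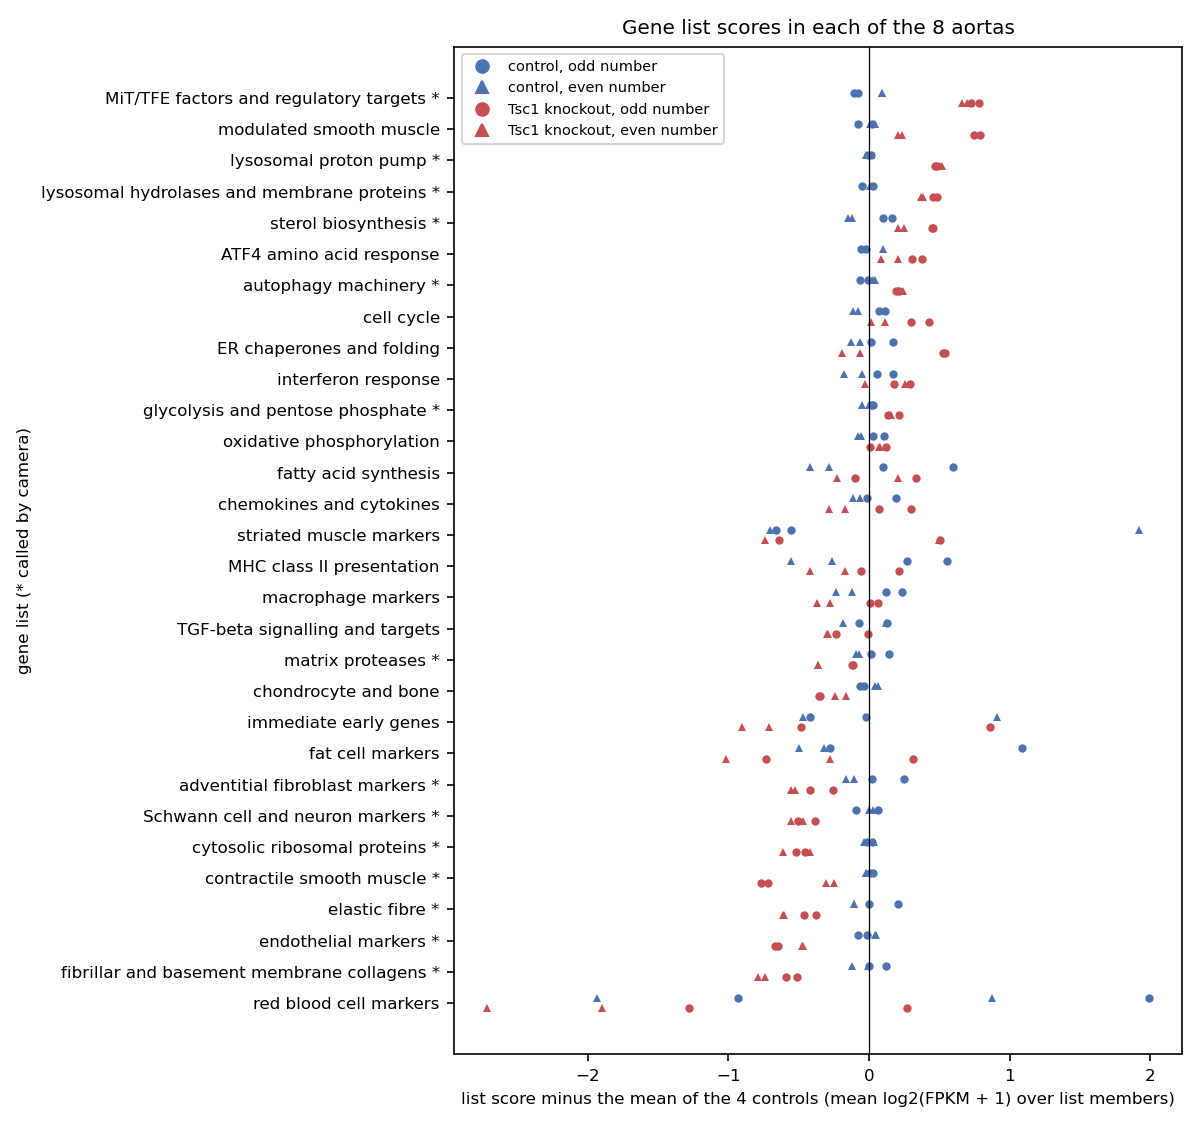
Scores of the 30 tested gene lists (mean log2(FPKM + 1) over the members) in each of the 8 aortas, minus the mean of the 4 controls, 1 point per aorta, with odd and even replicate numbers by shape and an asterisk on lists called by camera. The proton pump scores of knockouts lie apart from those of controls by 0.49 on average, while the striated muscle score of control 4 lies 1.92 above the control mean.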

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

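The rule for libraries that stand apart was fixed in advance, and no explanation is offered here for single genes. In 9 of 214 groups of 4 libraries (each named gene's FPKM and each list score, per genotype) 1 library lay far from the other 3. Chance alone flags about 1 in 20 such groups, or 10.7 here. Among list scores, control 4 had a striated muscle score of 3.86 against 1.24 to 1.38 in the other controls, and control 1 a fat cell score of 5.62 against 4.03 to 4.26. Among genes, Acacb was at 8.36 FPKM in control 1 (others 3.55 to 4.20), Col15a1 at 189 in control 4 (162 to 164), Flt1 at 3.27 in control 3 (4.10 to 4.26) and Tnfrsf11b at 7.20 in control 2 (6.22 to 6.38). In the knockouts, Slc2a1 was at 46.8 FPKM in number 4 (44.3 to 44.7), Atf4 at 74.8 in number 4 (97.7 to 101) and Ifit2 at 16.5 in number 3 (20.6 to 20.9). For Col15a1, Flt1, Tnfrsf11b, Slc2a1, Atf4 and Ifit2 the outlying library stayed on its own group's side of all 4 libraries of the other genotype, and for Acacb it lay above 1 knockout library.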

How the results depend on the processing

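The fits with odd or even number were chosen after the data were seen. Counts of called genes stayed within 1.5 times their values except with a minimum log2 change of 1, which left 206 higher and 161 lower by its construction. Each library left out in turn gave 1696 to 1889 higher and 1454 to 1620 lower genes. With an estimated correlation 1 list was higher and 0 lower, and with exact permutation of list scores 0 and 0, since the smallest adjusted p was 0.0536. For 13 of the 14 called lists the estimated correlation gave the highest p of the alternatives, and for the proton pump the permutation did. The replicate number as a block gave 2349 higher and 2122 lower genes. Same-numbered control and knockout deviations correlated at 0.066, 0.138, 0.135 and 0.173 for numbers 1 to 4, and 3 of 8 libraries correlated best with their own number, so the numbers were not taken as pairs. The lists that changed direction had no call before or after: ATF4 at a mean of 5 FPKM (camera adjusted p = 0.922), striated muscle at 5 FPKM (0.667), with median-of-ratios (0.922) and quantile scaling (0.931) and without control 4 (0.821), knockout 2 (0.665) or knockout 3 (0.641), and MHC class II with the fat cell covariate (0.921), in even-numbered libraries (0.460) and without control 3 (0.766). Over all 8 libraries left out in turn, whether or not the direction changed, the adjusted p was 0.641 to 0.864 for striated muscle and 0.213 to 0.920 for MHC class II. Odd-numbered libraries alone reversed fatty acid synthesis (0.679), oxidative phosphorylation (0.828) and immediate early genes (0.828), and even-numbered ones ER chaperones (0.635). The cause was not tested. Among 3893 called genes, 2461 were called again in the odd-numbered and 2498 in the even-numbered libraries alone. The called genes tested again kept their sign in every alternative but quantile scaling (99.9%). For the 1924 higher and 1672 lower genes without overlap between groups, any subset of the libraries must give the same sign. The kept sign in subsets is thus no independent support. Over the named genes, 1186 values in alternatives on all or fixed sets of libraries kept direction and call, 27 lost the call and 10 gained one. With 1 library left out the counts were 590, 25 and 1. The absolute depth is unknown, so for genes near 1 FPKM that did not pass a difference was not detectable at this depth.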

Other observations

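The lists of translation factors, iron handling and potassium channels, and the tests of odd against even numbers, Cry1 and endothelial markers, were chosen after the values were seen. The camera p-values of these lists were adjusted over these lists alone, so they are not comparable with those of the fixed lists. They give no independent support, since the lists were chosen from the same data. The test near Tsc1 and the counts of other divisions of the libraries were planned.

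Transcripts of the translation machinery other than ribosomal proteins fell as well. Of 19 translation factors and related transcripts, 16 fell, 0 rose and 3 did not pass, with a median log2 difference of -0.41 (limma camera adjusted p = 8.64e-10, but adjusted p = 0.0558 with an estimated correlation). The elongation factor Eef1a1 fell from 3593 ± 187 to 2384 ± 141 FPKM (log2 difference -0.59, SE 0.06, adjusted p = 2.81e-04), Tpt1 from 2327 ± 106 to 1729 ± 126 FPKM, and Gnb2l1, the ribosome-bound protein RACK1, from 496 ± 26.7 to 338 ± 14.7 FPKM. The 91 other coding transcripts under 1000 bases with a mean of at least 100 FPKM had a median log2 difference of -0.05.

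Genes of iron handling and oxidative stress rose. Of 17, 13 rose, 0 fell and 4 did not pass, with a median of 0.44 (limma camera adjusted p = 1.56e-05, and adjusted p = 0.00948 with an estimated correlation). The ferritin chains Fth1 and Ftl1 rose from 3791 ± 40.9 to 5816 ± 303 FPKM and from 707 ± 31.4 to 1409 ± 411 FPKM, and Hmox1, which breaks down heme, rose from 6.59 ± 0.195 to 14.5 ± 0.808 FPKM (log2 difference 1.03, SE 0.06, adjusted p = 1.68e-05). Nqo1, an oxidative stress enzyme, had a log2 difference of -0.24 and did not pass. Among 15 potassium channels and channel subunits 6 rose and 3 fell. The list as a whole was not called (limma camera, adjusted p = 0.267). Besides Kcnk3, the sodium-activated channel gene Kcnt1 rose from 0.164 ± 0.0522 to 7.04 ± 1.75 FPKM and Abcc9, the sulfonylurea receptor of vascular potassium channels, from 66.7 ± 3.35 to 208 ± 14.1 FPKM, while Kcnn4, a calcium-activated channel, fell from 4.25 ± 0.931 to 1.38 ± 0.285 FPKM.

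Of the 35 divisions of the 8 libraries into 4 and 4, only 1, the genotype, called as many as 3893 genes. The highest other value was 45 genes, for odd against even numbers. Every other division has both genotypes on each side, so the genotype difference widens the spread within sides and lowers its count. With genotype in the limma model, 651 genes were higher and 452 lower in even than in odd numbers, of 12107 tested. With 35 divisions, the first rank of the genotype does not by itself exclude chance. Nor do the list counts exclude it. In 12 of the 35 divisions, the genotype included, camera called at least the 14 lists of the genotype, with up to 20 in another division. Of the other 11, 9 set 3 libraries of one genotype with 1 of the other and so still hold part of the genotype difference. Among the 18 divisions with 2 libraries of each genotype on each side, the count ran from 0 to 17 lists. Most of these divisions called at least 4 lists, and 2 reached 14, 1 of them odd against even numbers with 17. Camera at the preset correlation thus called lists also where genotype was balanced. Within the odd-numbered libraries alone genotype called 6 lists higher and 8 lower, and within the even-numbered ones 8 and 9.

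The odd-numbered and even-numbered libraries differed in clock genes in both genotypes. Dbp, a clock-driven transcription factor, had 6.73, 102, 4.75 and 113 FPKM in controls 1 to 4 and 20.5, 96.8, 27.4 and 104 in knockouts 1 to 4, and Arntl (BMAL1) had 16.4, 2.52, 19.3 and 4.53 in controls and 10.5, 1.15, 11.2 and 1.67 in knockouts. The 12 evening-phase clock genes had a median even-minus-odd difference of 1.26 (log2), and 1.23 after a trend on transcript GC content and length was removed, which argues against such a bias between library batches as the whole cause. The 5 morning-phase genes had a median of -1.63, the opposite direction, in both genotypes (-1.53 in controls, -1.72 in knockouts), which is consistent with tissue taken at another time of day, a time the labels do not give. Cry1 was higher in even than in odd numbers in knockouts (1.53, 2.76, 1.46 and 2.6 FPKM in 1 to 4) and lower in controls (3.21, 1.07, 3.53 and 1.2), an interaction of 1.60 on the log2 scale (limma interaction fit, adjusted p = 1.27e-04 over the 17 clock genes, of which 7 passed, among them Dbp with -1.98), so another sampling hour or clock phase of the knockouts may add to genotype differences, in clock genes or in others, and these stay open.

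The fall of endothelial markers was set against dilution by a larger share of smooth muscle, which lowers all other cell types alike. The endothelial score changed by -0.57 and the macrophage score by -0.14. The difference of -0.42 had an exact permutation p of 0.171 (n = 4 against 4), a test that ignores the spread between odd and even numbers. It was -0.47 among the odd-numbered and -0.38 among the even-numbered libraries. With odd or even number in a linear model its SE was 0.04. Against the fibroblast score the endothelial difference was -0.13 (SE 0.06 in the same model, exact permutation p = 0.486). Against the Schwann cell score it was -0.09 (SE 0.07, exact permutation p = 0.429). Equal dilution of endothelial cells and macrophages is thus argued against only by the linear model, chosen after the data were seen. The fibroblast and Schwann cell scores fell by amounts nearer to the endothelial one (-0.44 and -0.48). Dilution of these cell types therefore stays open, as does dilution together with a gain of macrophages. Of the 17 endothelial markers 16 had a negative difference (median -0.75), but fewer endothelial cells and less RNA per endothelial cell cannot be told apart, since whole-tissue RNA holds no cell numbers.

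Ptgds, which had the largest rise among the genes taken by the fixed rule, lies 3171182 bases from Tsc1 on chromosome 2, where DNA of another strain could remain beside a floxed allele. Kcnt1 (log2 difference 2.76), Uap1l1 (1.98) and Dpp7 (1.80), picked after the values were seen, also rose within 5 Mb of Tsc1, and Cercam fell (-1.09). Among the 154 tested genes within 5 Mb of Tsc1, 33.1% were called, against 32.2% elsewhere (Fisher's exact test, p = 0.795, odds ratio 1.04, 95% interval 0.728 to 1.47). A raised share of called genes across the segment is thus not seen. The single genes stay open, and these 5 are the genes of the segment called with an absolute log2 difference of at least 1 (Fisher's exact test against the rest, p = 0.812).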
